A study of Mus musculus with 2 samples.

How the data were processed

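Embryos of the ICR strain carried Hcn4-CreERT2 and a Rosa-tdTomato reporter, with either floxed or intact Isl1, per the labels. Tamoxifen was given at embryonic day 10.5 and tissue was taken 36 hours later, per the labels. The stage label gives embryonic day 12.5, which is later than these 36 hours, and the protocol gives a range that ends there. Per the labels' protocols, fluorescent nodes of 1 genotype were pooled and digested with collagenase and trypsin, endothelial cells were removed with CD31 microbeads, and tdTomato-positive cells were sorted by flow cytometry. Messenger RNA was captured with oligo(dT) beads from 10 ng of total RNA, made into libraries with a SMARTer cDNA kit and sequenced in 90 bp read pairs on a HiSeq 2000, per the labels' protocols. The number of embryos in each pool is not given in the sources used here. Each genotype has 1 library, taken as the control group and the Isl1 mutant group from the labels.

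Trim Galore, FastQC, TopHat2 and Bowtie2, and the genome build mm9, are named in the submitters' processing notes, with no versions. The tool that made the gene table is not given in the sources used here. The deposited table lists 12557 Ensembl genes with 12446 symbols, their mm9 coordinates and the constitutive exons used, per the file headers. It holds 1 value per gene and library, and the authors' unit is not named in the header. The values were identified as RPKM, read numbers divided by exon length and library total, from their steps: for 284 small RNA genes with 1 exon, the deposited value times the gene's length was a whole number of reads within 0.01 in 284 genes of the control library and 276 of the mutant library, with the other 8 at a fill value. These steps gave library totals of 110117186 and 119018888 reads. The deposited log2 fold change by the authors equals the log2 ratio of both RPKM values with no pseudocount, with a largest difference of 1.89e-07. For Isl1 the authors' deposited table gives -2.33. The deposited signed fold, a score by the authors that is negative where the control is higher, was not used further. In each gene at least 1 library reaches 1 RPKM, the lowest such value being 1.000765778.

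A fill value, worth 1.44 control reads or 1.56 mutant reads, stands for 35 genes in the control library and 71 in the mutant library. A fold against it would be a bound set at 3 reads, and no such fold is printed. Whole reads were recovered from the steps for 12457 genes (99.2%). The number recovered is the smallest that fits both values, so the true number can be a multiple of it and the intervals can be wider than needed. Fold intervals are exact conditional binomial (Clopper-Pearson) 95% intervals on these reads and cover counting error only, as mates of a pair and PCR copies are not independent.

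The test design, the gene lists and the rule for named genes were fixed before the data were examined. A gene counts as higher or lower by size when log2((mutant RPKM + 1)/(control RPKM + 1)) is at least 1 in size and the gene reaches 5 RPKM in at least 1 library. This scale understates the change of low genes, and the folds printed in the text are ratios of RPKM without a pseudocount. For a symbol with several entries, that with the highest mean was kept. Across 5279 genes at 5 RPKM or more in both libraries the median log2 ratio was -0.07, and the values were used as deposited. For 30 gene lists (487 genes, 378 in the table) the median log2 ratio over members at 1 RPKM or more in at least 1 library was placed among the medians of 10000 random lists of equal size, matched on expression in 20 bins. Counts of members at least 2-fold higher or lower use the log2(RPKM + 1) scale and the same floor of 1 RPKM, and counts of members higher or lower have no minimum size. A list stands apart outside percentiles 2.5 and 97.5, as a description of these libraries, and lists with under 3 measured members were not compared.

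Genes named in the text are Isl1, a fixed core list, the 12 protein-coding named genes with the highest and the 12 with the lowest ratio at 5 RPKM or more, up to 4 members of each list with the largest ratio at that level, and list members at least 2-fold different. Genes given as overlap partners are outside that rule. Some genes that the rule names are not reported here, while list medians and counts include them. Transcript lengths for 12069 genes (96.1%) were the union of exons in GENCODE release M 21, matched by Ensembl identifier, with no coordinates taken from that build. Alternatives were other pseudocounts, scalings, floors, thresholds, expression bins and means in place of medians. One more, chosen after seeing the data, subtracted the median ratio of 10 level by 5 length bins.

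The scripts were tested on simulated data for this comparison. In 12557 simulated genes of which 200 were changed 3-fold, the size rule recovered 100% of the changed genes and called 0 unchanged ones. The changed genes were drawn from better expressed ones and the simulated noise was counting noise alone, so this outcome was near certain. It checks the scripts and gives no error rate for the real libraries, which also differ in pool, handling and PCR. The read recovery gave the exact ratio of reads in 100% of genes but the exact number in 83.0%, so that read numbers are given as the least that fit. Intervals made from the true simulated read numbers held the true fold in 96.6% of 1000 genes. Intervals made from recovered reads were not checked in this way. Of 100 unchanged random lists of 18 genes, 5 lay outside the tails, against 100 of 100 lists shifted by -0.7. The unchanged lists were themselves random draws, so the tails fixed this share in advance. It gives no error rate for the real lists, whose genes are related. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.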

Results

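RNA sequencing was carried out on cells sorted from the mouse sinoatrial node, the group of specialised heart muscle cells that sets the heart rate. The cells carried Hcn4-CreERT2, a tamoxifen-inducible recombinase made where the pacemaker channel gene Hcn4 is active, and a red fluorescent reporter that recombination switches on. Embryonic tissue was taken 36 hours after tamoxifen was given. There were 2 libraries, 1 from pooled Isl1 mutant embryos with floxed Isl1 and 1 from pooled control embryos with intact Isl1. The expression values rested on 110117186 reads in the control library and 119018888 reads in the mutant library. With 1 library per genotype there is no replicate error, no test was made, and differences are described by size. Intervals beside a fold are exact 95% intervals for counting error only, since reads copied by PCR are not independent molecules.

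Isl1 itself, which encodes a LIM-homeodomain transcription factor, was given first as a check of the genotypes. Isl1 (chromosome 13, 117088478 to 117099896, mm9) stood at 7.65 RPKM in the control library and at 1.52 RPKM in the mutant library. The value was 5.02-fold lower in the mutant library (interval 4.53 to 5.56, from at least 2122 and 457 reads) and 19.9% of control. The deposited values cover the constitutive exons of the gene, and the labels do not say which part is floxed, so reads from outside the removed part may remain in the mutant value.

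The first question was how far the transcriptome of the sorted cells differed between the genotypes. The highest ratios included those of Nppa and Nppb, the natriuretic peptide genes, of Lims2, Cplx2 and Acta1, and the lowest those of Hbb-y, a globin gene, of Laptm5, Arpc3 and Pdgfra. Of 6343 genes at 5 RPKM or more in at least 1 library, 64 were at least 2-fold higher in the mutant library and 170 were at least 2-fold lower, on the log2(RPKM + 1) scale. These were 1.01% and 2.68% of the genes, and 5354 genes (84.4%) lay within 1.5-fold. Among them, 44 of the higher and 133 of the lower genes were protein-coding genes with a gene name. The ratio moved with expression level. Its median was -0.62 (log2) below 2 RPKM, -0.18 between 5 and 10 RPKM and 0.09 at 100 RPKM or more, taken over the geometric mean of both libraries. With this trend and that of transcript length removed, a correction chosen after seeing the data, the counts were 82 higher and 92 lower.

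The 12 named genes with the highest ratios began with Nppa, the atrial natriuretic peptide gene, at 168 RPKM in the control library and 861 RPKM in the mutant library. This was 5.13-fold higher (interval 5.05 to 5.21). Nppb, which encodes the related B-type peptide and lies beside Nppa on chromosome 4, was 6.16-fold higher (2.44 to 15.02 RPKM). Acta1, the skeletal muscle alpha-actin gene, was 4.17-fold higher (161 to 672 RPKM). Tnni2 and Tnnt3, the genes of fast skeletal troponin I and troponin T, were 4.57-fold and 3.52-fold higher, and Lmod3, an actin filament nucleator of striated muscle, was 4.71-fold higher. Cplx2, which encodes a regulator of vesicle fusion, went from 0.564 to 5.87 RPKM, 10.4-fold higher. Lims2, a focal adhesion gene, was 5.51-fold higher and Pde10a, a cyclic nucleotide phosphodiesterase gene, 3.85-fold higher. Ctgf, a matricellular growth factor gene, was 2.95-fold higher, Slc16a3, a lactate transporter gene, 2.84-fold higher, and the keratin gene Krt19 2.95-fold higher. The library kit does not mark strand, and 37 of the 127 genes named by rule overlap another gene of the table. Nppa reads therefore cannot be separated from those of the opposite-strand gene Gm13054, at 138 and 703 RPKM, nor Ctgf reads from those of Gm15270, at 17.97 and 50.1 RPKM.

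The 12 named genes with the lowest ratios began with Hbb-y, an embryonic beta-like globin gene, at 178 RPKM in the control library and 24.9 RPKM in the mutant library, 7.14-fold lower (interval 6.84 to 7.45). Adult globin genes were also in this group, with Hba-a1 5.96-fold, Hba-a2 5.23-fold, Hbb-b1 5.05-fold and Hbb-b2 4.87-fold lower. Each of these pairs is nearly identical in sequence, so the division of reads within a pair is uncertain. Laptm5, a lysosomal membrane protein gene of blood cells, was 7.76-fold lower (23.2 to 2.99 RPKM), and Car2, a carbonic anhydrase gene abundant in red cells, 5.50-fold lower. Pdgfra, a growth factor receptor gene of mesenchymal cells, went from 9.53 to 1.45 RPKM, 6.59-fold lower (interval 6.27 to 6.93). Mfap4, a gene of extracellular microfibrils, was 4.41-fold lower. Mylk, the myosin light chain kinase gene, was 8.52-fold lower (interval 6.39 to 11.6, from at least 418 and 53 reads). Arpc3, a subunit gene of the actin-nucleating Arp2/3 complex, was 5.83-fold lower, and D4Wsu53e 5.26-fold lower.

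**Figure D1:**
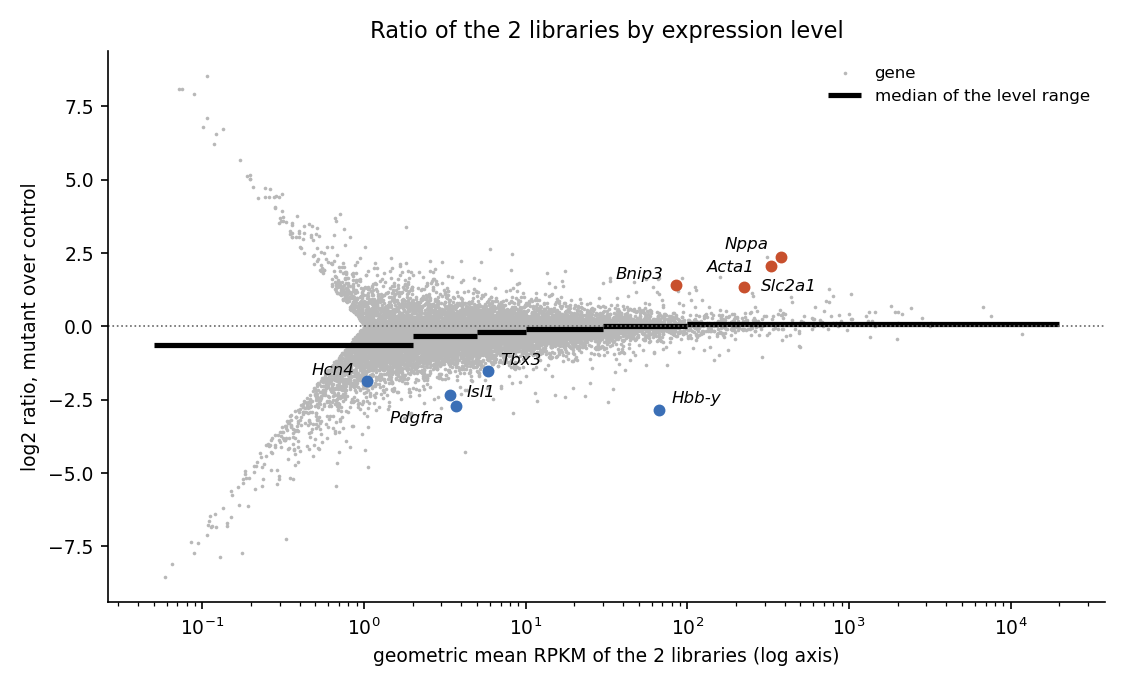
Each point is a gene, placed by the geometric mean RPKM of both libraries (log axis) and by the log2 ratio of mutant over control, and black bars are medians of level ranges. The median moves from -0.62 below 2 RPKM to 0.09 at 100 RPKM or more, with Nppa and Acta1 far above it and Hbb-y, Isl1, Tbx3 and Pdgfra far below.

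The study's title names genes important for the function of the sinoatrial node, and the pacemaker programme was compared next. Pacemaker genes were mostly lower in the mutant library. Tbx3, a transcriptional repressor gene of the pacemaker programme (chromosome 5, 120120678 to 120134733), went from 9.90 to 3.45 RPKM, 2.87-fold lower (interval 2.74 to 3.005). Hcn4, the gene of the main pacemaker channel (chromosome 9, 58671319 to 58708762), went from 1.99 to 0.541 RPKM, 3.67-fold lower (interval 2.80 to 4.85). It lies under the level of 5 RPKM that the size rule asks for. Genes below 2 RPKM, its level range, had a median log2 ratio of -0.62, beside -1.88 for Hcn4. Among calcium channel genes, Cacna2d2 was 2.72-fold lower (14.2 to 5.24 RPKM) and Cacna1d, the gene of the L-type channel Cav1.3, 2.23-fold lower (12.1 to 5.40 RPKM). Bmp4, a growth factor gene, was 2.14-fold lower (53.04 to 24.7 RPKM).

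Of 22 listed pacemaker genes, 18 were measured, of which 15 were lower and 3 higher, and 4 were at least 2-fold lower. The median log2 ratio was -0.71, below all medians of 10000 random lists matched on expression level, whose central 95% ran from -0.29 to 0.07. Shox2, a homeobox gene required for the node, was 1.72-fold lower (14.8 to 8.64 RPKM). Kcnj3, the gene of the acetylcholine-gated channel subunit GIRK1, was 1.93-fold lower, while Kcnj5, which encodes its partner GIRK4, was 1.07-fold higher (27.8 to 29.8 RPKM). Tbx18, a T-box gene of the sinus venosus, was 1.25-fold lower (4.77 to 3.81 RPKM). Gene pairs that overlap on opposite strands include Tbx3 with Gm2301, Bmp4 with Gm15217 and Shox2 with Rsrc1. Only the ends of these genes overlap, and reads from the shared stretch cannot be separated. Hcn2, Cacna1g and Gjd3 of this list, and Nkx2-5 of the next, were not analysed here.

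**Figure D2:**
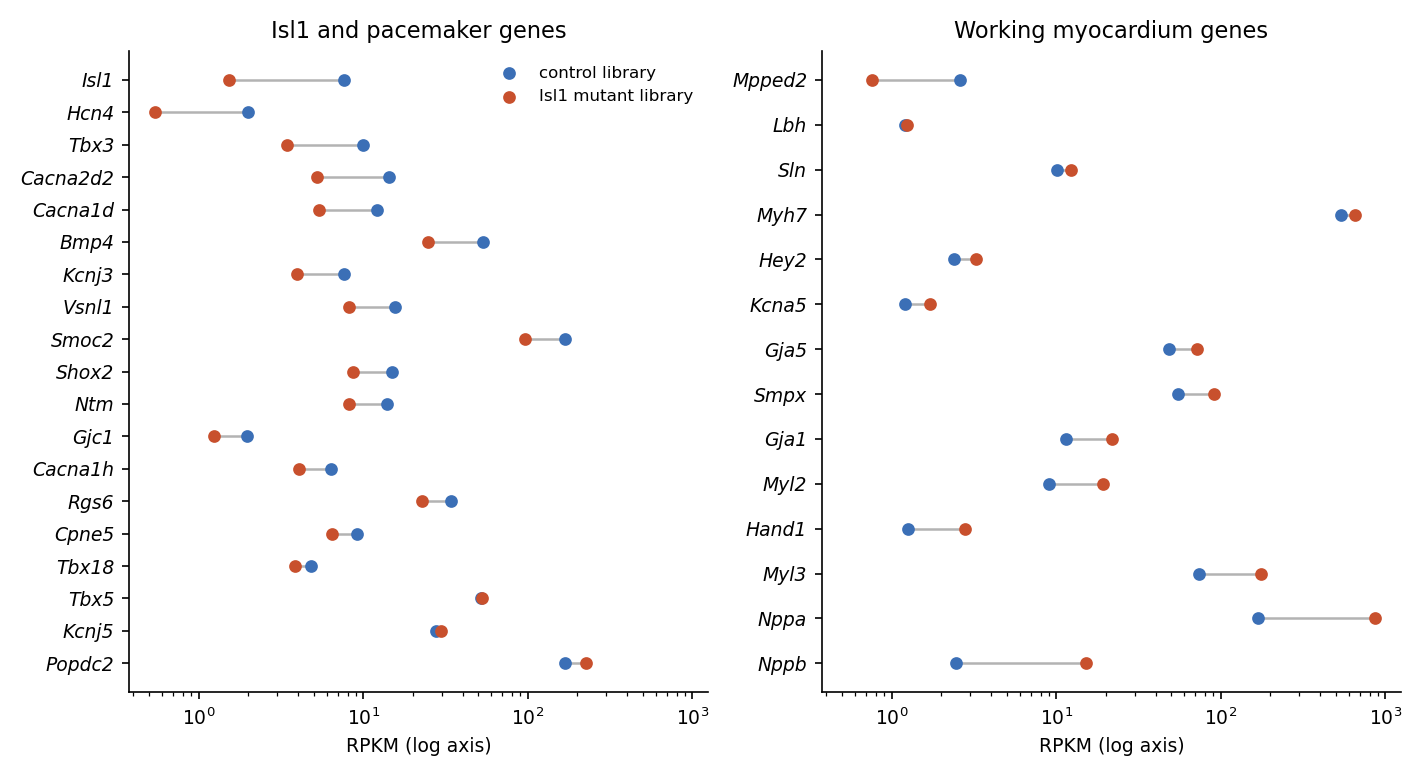
RPKM on a log axis of Isl1 and the measured pacemaker genes (left) and of genes of working atrial and ventricular muscle, leaving out 2 lower ones not reported here (right), with a blue point for the control library, a red point for the mutant library and a line joining them. On the left most red points lie below the blue ones, as for Tbx3 at 9.90 and 3.45 RPKM, and on the right most lie above, as for Nppa at 168 and 861 RPKM.

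Genes of the working heart muscle, the contracting muscle outside the node, went the other way. Of 12 genes of working atrial muscle, 9 were measured, 7 of them higher, and the median log2 ratio was 0.56, above all matched random medians. Besides Nppa and Nppb, the gap junction genes Gja1 and Gja5 were 1.89-fold (11.4 to 21.6 RPKM) and 1.49-fold higher (48.1 to 71.5 RPKM). Of 10 genes of ventricular muscle, 7 were measured and 6 were higher, with a median of 0.32 at percentile 99.35. Of the 7 genes, 2 were at least 2-fold higher and 1, Mpped2, was at least 2-fold lower (2.60 to 0.753 RPKM). The myosin light chain genes Myl3 and Myl2 were 2.39-fold (73.1 to 175 RPKM) and 2.12-fold higher (9.02 to 19.2 RPKM), and Myh7, the slow myosin heavy chain gene, 1.22-fold higher.

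Sarcomere genes, with 25 of 26 measured, had a median of 0.32, above all matched random medians. Of the measured genes 17 were higher and 8 lower, with 0 at least 2-fold higher and 2 at least 2-fold lower. Actc1, the cardiac alpha-actin gene, went from 5374 to 8539 RPKM (1.59-fold higher), and Myl7, the atrial light chain gene, was 1.54-fold higher. Smyd1, a muscle-specific methyltransferase gene, was lower by 2.77-fold (68.4 to 24.7 RPKM). With the mean in place of the median the sarcomere list gave 0.088 and lay inside the range of random lists.

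Genes of calcium handling lay near 0, with a median of -0.02 over 17 of 18 genes at percentile 74.1. Casq1, a calcium store protein gene of the sarcoplasmic reticulum, was 2.02-fold higher (307 to 621 RPKM), and Ryr2, the calcium release channel gene, 1.55-fold lower (10.4 to 6.72 RPKM). Genes of potassium and sodium channels, with 15 of 25 measured, had a median of 0.13 at percentile 99.52. This rested on genes of low level, since members at 5 RPKM or more gave -0.37 at percentile 6.34. In that list Atp1b1, a subunit gene of the sodium pump, was 1.64-fold lower, and Kcnh2, the gene of the ERG potassium channel, differed by 1.04-fold with an interval that includes no difference (0.999 to 1.08). Ank2, the gene of the membrane scaffold ankyrin-B, was 2.08-fold lower (3.85 to 1.85 RPKM) and overlaps Larp7 on the same strand. It lies under 5 RPKM in both libraries, so the size rule does not count it. Genes between 2 and 5 RPKM, its level range, had a median log2 ratio of -0.31, beside -1.06 for Ank2.

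Metabolic genes were compared in 3 lists. Genes of hypoxia and glycolysis were higher in the mutant library, with 20 of 21 measured genes higher, 4 of them at least 2-fold, and a median of 0.67 above all matched random medians. Bnip3, a hypoxia-induced mitophagy gene, was 2.63-fold higher (52.5 to 138 RPKM), Slc2a1, the glucose transporter GLUT1 gene, 2.53-fold higher (140.3 to 355 RPKM), Ndrg1, a hypoxia-induced stress gene, 2.96-fold higher (2.98 to 8.81 RPKM) and Ldha, a lactate dehydrogenase gene, 2.06-fold higher (550 to 1135 RPKM). In the same libraries, genes of oxidative phosphorylation were higher in 21 of 21 measured cases, none by 2-fold, with a median of 0.31 at percentile 99.995. Cox6a2, a muscle subunit gene of cytochrome oxidase, was 1.70-fold higher and Ndufa4 1.501-fold higher. Genes of fatty acid oxidation had a median of 0.04 over 16 genes at percentile 81.6, while Cpt1a, the gene of the non-muscle carnitine palmitoyltransferase, was 2.28-fold lower (9.58 to 4.199 RPKM).

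Markers of other cell types that the dissected tissue holds were measured beside these groups. Erythroid genes were lower in 11 of 11 measured cases, 10 of them at least 2-fold, with a median of -1.71. Macrophage and blood markers were lower in 9 of 9, with a median of -0.89 at percentile 0.07. Csf1r, the receptor gene of the macrophage growth factor, was 5.50-fold lower (6.39 to 1.16 RPKM) and C1qb, a complement gene, 3.33-fold lower. Fibroblast and cushion mesenchyme genes were lower in 11 of 11, with a median of -1.02, including Pdgfrb at 2.70-fold lower and Col3a1 at 2.51-fold lower (87.6 to 35.0 RPKM). The erythroid and fibroblast medians lay below all matched random medians.

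Extracellular matrix genes, which share 4 members with the fibroblast list, were lower in 25 of 26 measured cases, 7 of them at least 2-fold, with a median of -0.84, below all matched random medians. Nid1, a basement membrane gene, was 3.57-fold lower (8.67 to 2.43 RPKM), Tnc, the tenascin-C gene, 3.26-fold lower (8.24 to 2.53 RPKM) and Col1a2, a collagen type I gene, 2.45-fold lower (58.7 to 23.9 RPKM). Smooth muscle genes had a median of 0.44 over 7 genes at percentile 99.9, with Tagln, an actin-binding protein gene, 2.26-fold higher (31.8 to 71.9 RPKM) and Acta2, the smooth muscle actin gene, 1.78-fold higher (566 to 1008 RPKM). Mylk, of the same list, was lower as given above.

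Other cell type lists stayed inside the range of matched random lists. Endothelial and endocardial genes, whose cells the protocol depleted with CD31 beads, had a median of -0.54 over 11 genes at percentile 10.8, with the receptor genes Kdr and Tek 2.31-fold and 1.57-fold lower. Epicardial genes had a median of -0.26 over 10 genes at percentile 21.005, although Krt19 is among them. Genes of neural crest, glia and neurons had a median of -0.06 over 10 genes at percentile 88.7. In that list Nefl, a neurofilament gene, was 2.28-fold higher (3.36 to 7.65 RPKM) and Ednrb, the endothelin receptor B gene, 1.61-fold lower. Liver genes had a median of -0.44 over 6 genes at percentile 28.7, with the alpha-fetoprotein gene Afp 3.57-fold lower (10.6 to 2.98 RPKM). Of 10 genes of foregut and lung epithelium 2 were measured, too few to compare, and these keratin genes, Krt8 and Krt18, were 1.29-fold and 1.56-fold higher.

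Signalling and proliferation lists were compared next. BMP signalling genes had a median of -0.40 over 11 genes at percentile 1.98, with the targets Id2 and Id3 1.43-fold and 1.38-fold lower and Bmp5 1.78-fold higher. Bmp4, shared with the pacemaker list, was the only member at least 2-fold lower. The BMP list lay inside the random range when the pseudocount was 5, when the level floor was 5 RPKM or when the mean replaced the median. Wnt signalling genes were lower in 10 of 11 cases with a median of -0.42 at percentile 9.46, including Lef1, a Wnt-responsive transcription factor gene, 1.96-fold lower (9.08 to 4.64 RPKM), while Dkk3 was 1.86-fold higher (90.8 to 169 RPKM). With the level and length trend removed, or with a pseudocount of 5, the Wnt list lay outside the random range, at percentiles 2.28 and 1.60. Notch signalling genes had a median of -0.36 over 6 genes at percentile 44.9, with Hey1, a Notch target, 1.09-fold higher. Axon guidance and neurotrophic genes had a median of -0.35 over 14 genes at percentile 23.6, with the semaphorin receptor gene Nrp1 1.28-fold lower. Retinoic acid genes had a median of -0.26 over 9 genes at percentile 36.3, with the retinoic acid synthesis gene Aldh1a2 1.21-fold lower. Genes of the second heart field, the progenitor population that adds to both poles of the heart tube, had a median of -0.23 over 11 genes at percentile 37.9. In that list Osr1 was 2.13-fold lower (20.99 to 9.83 RPKM), and Mef2c, a muscle transcription factor gene, was 1.04-fold higher (29.1 to 30.1 RPKM).

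Cell cycle genes had a median of 0.02 over 34 genes at percentile 92.2 and none reached 2-fold, with the mitotic kinase gene Aurka 1.59-fold higher and Cdc20 1.44-fold lower. Targets of p53 had a median of -0.09 over 11 genes at percentile 60.9, with Mdm2 1.23-fold lower. Early response genes, which tissue dissociation induces, were lower in 15 of 16 cases with a median of -0.57, below all matched random medians. Fosb was 4.21-fold lower (5.22 to 1.24 RPKM) and the nuclear receptor gene Nr4a1 1.83-fold lower (120.4 to 65.9 RPKM). Genes of ATF4 and the unfolded protein response had a median of 0.30 over 12 genes at percentile 99.96, with the asparagine synthetase gene Asns 1.34-fold higher and Herpud1 1.36-fold higher. Of 29 lists compared, 7 lay below and 8 above the central 95% of their random lists, and some lists share members.

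**Figure D3:**
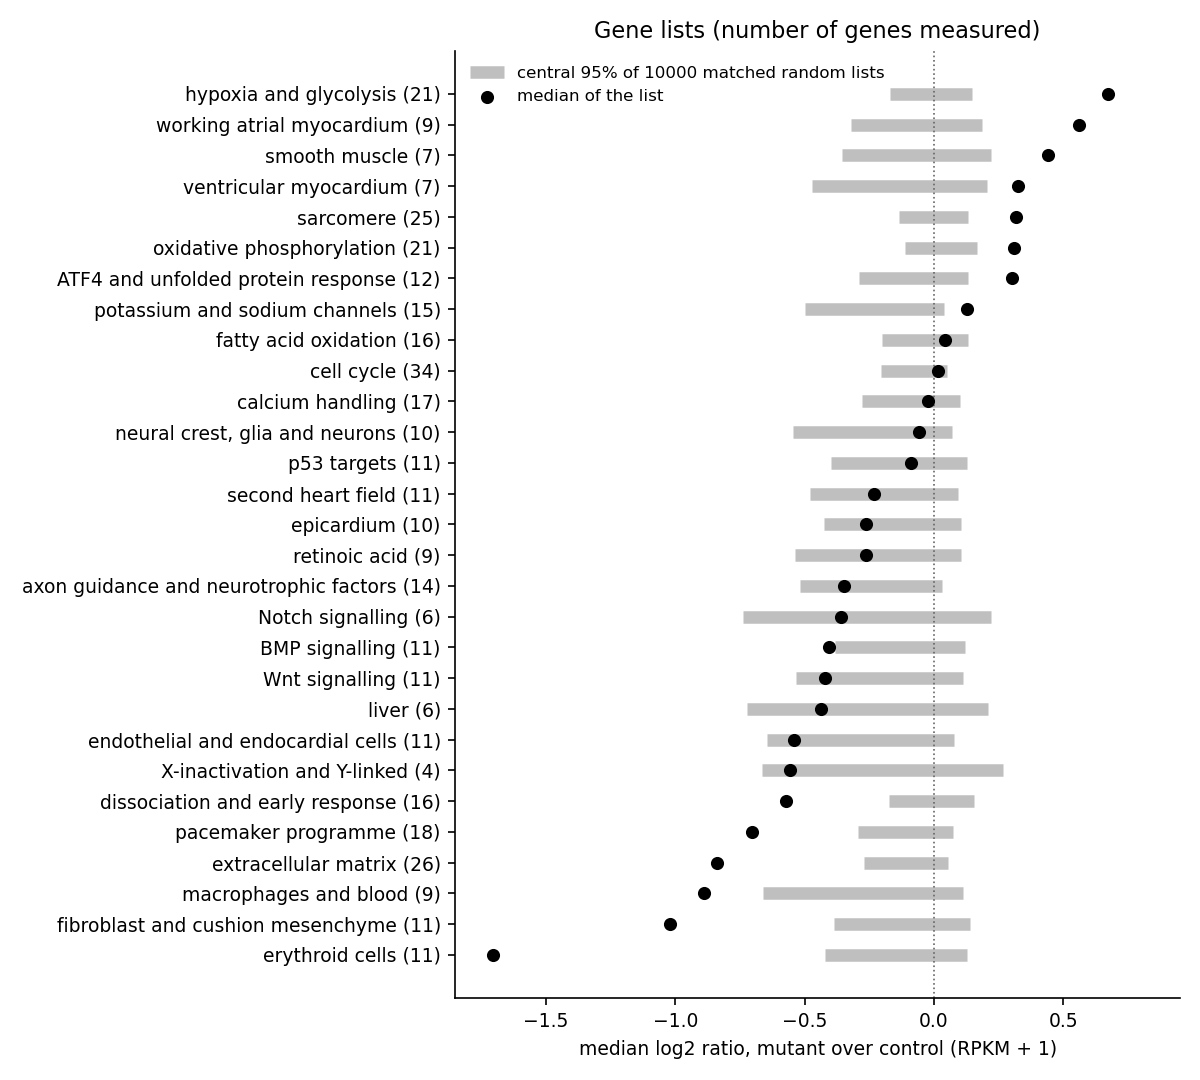
Median log2 ratio of mutant over control (RPKM + 1) for each of 29 gene lists (black points), with the number of genes measured in brackets and grey bars for the central 95% of 10000 random lists matched on expression level. Medians run from -1.71 for erythroid genes to 0.67 for hypoxia and glycolysis genes, and the pacemaker programme stands at -0.71.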

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

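The removal of the level and length trend and the matching of random lists on length were chosen only after the result was seen. Isl1 was lower in every setting: the log2 ratio was -2.33 without a pseudocount, -1.78 and -0.96 with pseudocounts of 1 and 5, and -1.64 with the trend removed. The counts of 64 higher and 170 lower genes depended on the settings. They were 36 and 36 with a pseudocount of 5, 139 and 489 with no level floor or a floor of 1, which are alike because the table has no lower genes, 36 and 32 with a floor of 20, 239 and 750 at 1.5-fold, and 6 and 15 at 4-fold. The lower count was 265 with a pseudocount of 0.1 and 92 with the trend removed. Higher genes were 27.4% of both counts together, against 47.1% with the trend removed. Of 296 list alternatives, 289 kept the side of the random range. In 10 of these, from 7 lists inside that range, the sign changed, so those lists have no settled direction. The sarcomere list gave 0.088 as a mean. The channel list turned to -0.37 with a floor of 5 RPKM, where fewer genes enter. The BMP list gave -0.19 with a pseudocount of 5, -0.33 with a floor of 5 RPKM and -0.34 as a mean, inside the random range. The Wnt list gave -0.24 with a pseudocount of 5 and -0.29 with the trend removed, outside it. The cause was not tested. Of 127 named genes 49 passed the size rule, 28 of them in every setting, and 0 of the 49 changed sign. A pseudocount cannot change a sign and the rescalings were small, so most settings could hardly have changed it. Among the other named genes the sign changed in 2, one being Kcnh2, which was slightly higher when centred or with the trend removed. Of 762 gene alternatives, 29 lost and 9 gained the 2-fold size. TMM was not run, as it was planned only for deposited counts. No paired analysis was possible because each genotype has 1 library, and no library could be left out. Depth limits low genes such as Hcn4, with at least 241 and 71 reads.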

Other observations

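Chosen only after the result was seen were the fast skeletal muscle list with its named genes and the tests on cell types, on blood markers, on pairs of genes and on the early response. The tests of the level and length trend were written before their results, on a correction chosen after seeing the data. Of 23 genes of fast skeletal muscle, 15 were measured, 13 were higher in the mutant library and 7 were at least 2-fold higher, with a median log2 ratio of 0.97. Besides Acta1, Tnni2, Tnnt3 and Lmod3, they included Ckm, the muscle creatine kinase gene (10.53 to 27.3 RPKM, 2.59-fold), and Myl1, a myosin light chain gene (168 to 370.3 RPKM, 2.21-fold). Without the 4 members among the 12 highest genes, the other 11 had a median of 0.56, with 9 above 0, against -0.31 to 0.18 for the central 95% of matched random lists. These 11 are not independent of the data, as the list was drawn up after the ratios were seen and holds Casq1, given above. Myh8, a perinatal myosin heavy chain gene, was 1.56-fold lower (2.74 to 1.76 RPKM), and Pygm, the muscle glycogen phosphorylase gene, 1.24-fold lower (169.0 to 136 RPKM).

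Transcription regulators, as the deposited table classes them, gave 17 of 549 lower (3.10%) and 0 higher by size, beside 2.68% lower and 1.01% higher over all genes. As ratios of RPKM without a pseudocount, 26 were at least 2-fold lower and 3 at least 2-fold higher. Besides Isl1, Tbx3, Smyd1 and Osr1, the lower ones included Myc, a growth regulator gene (8.89 to 1.98 RPKM, 4.49-fold), and Nfkb2, an NF-kappa-B subunit gene (5.33 to 1.59 RPKM, 3.35-fold), both named after their values were seen. Kinase genes gave 1 higher and 9 lower of 148, receptor genes 1 and 7 of 73, G protein-coupled receptor genes 1 and 2 of 21, and splicing regulators 0 and 1 of 183. Among genes that differ between the sexes, Xist, the X-inactivation RNA, went from 7.21 to 3.68 RPKM. The Y-linked genes Eif2s3y (9.31 to 5.95 RPKM) and Ddx3y (4.83 to 7.45 RPKM) moved apart. Both pools thus held transcripts of both sexes. The list of 4 such genes had a median of -0.56 at percentile 5.92. As it pools Xist with Y-linked genes, this median says nothing about the share of each sex in the pools.

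The pacemaker programme was lower in the mutant library, with a median of -0.71, while random lists matched on level and length reached -0.33 at the lower end of their central 95%, against that trend as the whole cause. More blood cells, macrophages or fibroblasts in the mutant sort would raise their markers, yet the highest of these 3 list medians was -0.89, each below its random range. More endothelial cells, which the CD31 beads would remove, or more epicardial or neural cells find no support in medians of -0.54, -0.26 and -0.059, with 9 of 11, 7 of 10 and 6 of 10 genes lower, but these lie inside their random ranges and leave such cells open. More working myocytes may be present and cannot be told apart from lower expression per cell. The log2 ratio of Hcn4 lay below that of Shox2, a difference of -1.10. The level trend enters this difference, as the median over all genes was -0.62 below 2 RPKM, the range of Hcn4. It was -0.09 between 10 and 30 RPKM, the range of Shox2. The level of either gene in working myocytes is not in these data, and loss of Isl1 stays open beside more working myocytes.

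Blood and connective tissue genes were lower in the mutant library, with medians of -1.71 (erythroid) and -1.02 (fibroblast). Matched random lists reached -0.42 and -0.43 at the lower ends of their central 95%, against the level and length trend as the whole cause. Fewer blood cells carried through the tdTomato sort may account for the first, but that 20 of 20 erythroid and macrophage markers were lower, such as Hbb-y at 178 and 24.9 RPKM, is the pattern itself and favours no cause. For the connective tissue genes, fewer fibroblasts in the sort and lower expression in the sorted cells cannot be told apart. The log2 ratio of Pdgfra lay below that of Dcn, a difference of -2.18, but the level of either in the other sorted cells is not in these data.

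Hypoxia and glycolysis genes were higher in the mutant library, with a median of 0.67. Random lists matched on level and length reached 0.11 at the upper end of their central 95%, against that trend as the whole cause. The early response list had a median of -0.57, against a stronger early response to dissociation over the sorted cells of the mutant pool as a whole. Blood, macrophage and fibroblast genes were also lower, so the response of the muscle cells alone cannot be told from this median. The early response list does not measure how long each pool was handled, so longer handling of the mutant pool is not excluded. Oxidative phosphorylation genes were also higher, with a median of 0.31, as were sarcomere genes, with a median of 0.32. Loss of Isl1, a larger share of muscle RNA and differences between the pools in embryo age or time before sorting stay open, untested with 1 library per genotype.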
